A study of Homo sapiens and Mus musculus with 80 samples.

How the data were processed

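The series holds 80 samples. RNA sequencing (RNA-seq) was done on 6 libraries of HCCLM3, a metastatic human hepatocellular carcinoma cell line, 3 with a control short hairpin RNA (shCtrl) and 3 with a hairpin against RFC3 (shRFC3). Single-cell RNA-seq was done on 2 mouse liver tumour samples, 1 with a control guide RNA (sgCtrl) and 1 with a guide against Rfc3 (sgRFC3). The other 72 samples are CUT&Tag libraries of HCCLM3 in 36 groups of 2 (G-quadruplex DNA, RFC3, RNA polymerase II forms and transcription proteins, by cell cycle phase or hairpin), which were not analysed here. The design text speaks of a single biological replicate per CUT&Tag condition while the sample titles number 2.

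For the cell line, the authors deposited a table of FPKM values (fragments scaled to transcript length and to the mapped fragments of each library) for 50868 genes with Ensembl identifiers and loci. HISAT2 2.0.4, StringTie 1.3.3b and edgeR are among the tools in the submitters' processing notes, and hg38 is the human build named there, with no role given for any of them. The labels' protocols name the VAHTS Universal V6 kit for RNA libraries. The aligner settings and the use of strand are not given in the sources used here. The columns carry names beginning with Plko and Sh1, numbered 1 to 3. They were taken as shCtrl and shRFC3 from these names alone, Plko being the usual name of the empty hairpin vector. FPKM values carry no read totals, so the depth behind each value is unknown. The labels describe the replicates as independent biological samples.

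FPKM values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend). Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, which left 14076, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The deposited values were used without further scaling. Gene lists (23, written from textbook knowledge) were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. Members were also counted with their p adjusted over the list alone. On simulated data with the means and spread of these libraries and 200 changed genes among the 14076, the fit recovered 0% of 1.5-fold changes, 43.0% of 2-fold changes and 85.5% of 4-fold changes, with 0, 7 and 9 false calls. The real comparison called 5898 genes, and with so many the adjusted threshold is less strict. These recovery rates therefore do not carry over to it. In a separate simulation without the 200 changed genes, camera called 20 of 20 lists shifted by 0.5 on the log2 scale and 0 of 20 unshifted lists. Genes were drawn independently of each other there, so it does not test the preset correlation.

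For the mouse tumours, the deposited matrices hold raw UMI counts for 32285 genes, made with Cell Ranger 7.0.1 per the file headers. Builds mm10 and GRCm38 are named in the submitters' processing notes, as is Seurat. The labels' protocols name the 10x Genomics Chromium platform. The matrices hold 10577 barcodes and 150153690 UMIs for sgCtrl, and 9662 barcodes and 104054078 UMIs for sgRFC3. Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. Mitochondrial UMIs exceeded that limit in 25.8% of the sgCtrl barcodes and 16.7% of the sgRFC3 barcodes. Scrublet, run per library in scanpy 1.11.5, marked 96 sgCtrl and 0 sgRFC3 cells as doublets at its automatic threshold, which had therefore not worked in sgRFC3. A common score of 0.25 was then set after seeing this, and it removed 118 and 109 cells. This left 7157 sgCtrl cells with a median of 11551 UMIs and 7382 sgRFC3 cells with a median of 6321 UMIs.

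Both libraries were clustered together (counts scaled to 10000 per cell and log transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1) into 23 clusters. Clusters were called by markers of 17 cell classes. A class needed at least 3 markers found in at least 20% of the cells of the cluster at 2-fold the level of the other cells, with no more markers of another class than of its own among the 10 leading genes, and a cluster of shallow cells also needed a marker of its own among them. The scoring of leading genes went through 3 versions. The first was written before any cluster was seen and is the one used. The others were tried after it had left clusters 0, 2 and 3 unnamed, and their values are among the alternatives. Those 3 clusters are compared by number.

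With 1 library per guide there was no test between the tumours, and no p-value, standard error or count of changed genes was made from cells. Shares are given with exact (Clopper-Pearson) 95% intervals and sums of UMIs with exact Poisson 95% intervals. These, and the limit of 3 counts where a count was 0, cover counting error only. Expression in a class is the summed UMIs of a gene scaled to 1000000 UMIs of the class (CPM), and a gene list is given as the median log2 ratio of its members (sgRFC3 over sgCtrl) with its percentile among 10000 random lists of the same size matched on expression in 20 level bins. Members with at least 20 UMIs over both libraries entered, 0.5 UMIs were added to each sum, and lists of at least 5 such members were used; these settings were chosen once the matrices had been seen but before any list value. The 95% interval of a list median was read from the ordered ratios of its members, so it covers their spread and not counting error. Proliferating cells are those with UMIs of at least 2 genes of the mitosis list after thinning each cell to 1000 UMIs. In simulated counts for 14387 genes, the exact intervals held the true ratio in 98.5%, 97.0% and 97.0% of genes changed 1.5-, 2- and 4-fold. The sums were drawn as Poisson counts, for which such intervals are exact, so this checks the calculation only. Variation between cells or animals was not simulated.

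Gene lists, cell class markers, the tests and the rule for named genes were fixed before the data were examined. In the cell line the named genes are RFC3, the 12 highest and the 12 lowest changed genes with a mean of at least 1 FPKM, a gene symbol and no overlap between the groups, up to 4 members per list (those changed most first), and the proteins profiled by CUT&Tag. In the tumours they are Rfc3, the 5 highest and 5 lowest ratios per class of at least 200 cells in both libraries, and up to 4 members per list. Some genes that the rule takes are not reported here. For the class rule, genes needed 100 UMIs, 100 CPM in one library and at least 0.5 of the level of all other cells, and mitochondrial, ribosomal, haemoglobin, Xist and Y-linked genes were left out. Alternatives were the pseudocount (0.1), the filter (none, or 1 FPKM), 2 other scalings, a replicate term, each library left out, a test against a 1.5-fold change, other set tests, other cell filters, doublets kept, other doublet threshold, Leiden resolution 0.5, naming versions, thinning, and at least 3 mitosis genes per cell. A first run of camera used a trended variance and left out lists of a single gene; the form fixed beforehand was restored, and the other is among the alternatives.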

Results

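Gene expression was measured in HCCLM3 liver cancer cells with a control hairpin or a hairpin against RFC3, with 3 RNA-seq libraries each, and in mouse liver tumours labelled with a control guide or a guide against Rfc3, with 1 single-cell library each. RFC3 is a subunit of the replication factor C clamp loader, which places the sliding clamp PCNA on DNA at replication forks. The summed FPKM of the cell line libraries lay between 227302 and 240875, with 21329 to 22369 genes above 0 per library. The tumour libraries gave 131637149 UMIs in the 7157 sgCtrl cells used and 90712567 UMIs in the 7382 sgRFC3 cells used.

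RFC3 was lower in each shRFC3 library than in each shCtrl library. Its level was 18.7 ± 0.685 FPKM (SD, n = 3) with shCtrl and 3.06 ± 1.03 FPKM (SD, n = 3) with shRFC3, which is 83.7% lower. The gene lies on chromosome 13 from 33818049 to 33966558 in the deposited table. Limma gave a log2 fold change of -2.31 (SE 0.19, adjusted p = 0.000245). The exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it can give.

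The first comparison asked how the transcriptome of the cell line changed with the hairpin. Of 14076 genes tested, 3308 rose and 2590 fell with shRFC3, 5898 together, and 1014 of these changed by at least 2-fold (2056 with a pseudocount of 0.1). Of the changed genes 56.1% were higher, against 51.8% after median-of-ratios scaling and 47.4% after quantile normalization, so the balance of higher and lower genes depends on the scaling. Inflammatory and interferon genes led the increases: CXCL8, a neutrophil-attracting chemokine, went from 1.47 ± 0.468 to 190 ± 21.9 FPKM (SD, n = 3 per group, log2 fold change 6.28, SE 0.17, adjusted p = 5.37e-06 by limma). Ribosome biogenesis and several replication genes were among the decreases. When genes had to change by more than 1.5-fold, limma's treat test called 777 genes, 564 higher and 213 lower. Without shRFC3 replicate 3, which stood apart from the other 2 on the first 2 principal components (72.4% and 15.2% of the variance), 7520 genes passed, 5628 of them shared with the full set. The lower genes numbered 1658, 1590 and 1625 without shCtrl replicate 1, 2 or 3.

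After CXCL8 came S100A9, a calcium-binding alarmin (log2 fold change 6.04), the chemokine CCL5 (6.02), STC1, a secreted glycoprotein (4.10), HSD11B1, which regenerates active glucocorticoid, the chemokine CXCL1 (3.93) and RSAD2, the antiviral protein viperin (3.67). GJA1, the gap junction protein connexin 43 (3.62), ISG15, a ubiquitin-like interferon product (3.49), 1 of the 2 entries named C11orf71 (3.47; the other, at -0.89, fell) and the cytokine IL6 (3.44) were also among the 12 highest. S100A9 went from 4.77 ± 0.905 to 376 ± 40.8 FPKM and CCL5 from 7.20 ± 2.74 to 517 ± 69.1 FPKM (SD, n = 3 per group). The largest adjusted p of these 12 genes was that of GJA1 (7.82e-05 by limma).

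Among the 12 lowest, ALPI, the intestinal alkaline phosphatase, fell most, from 14.3 ± 0.313 to 0.541 ± 0.111 FPKM (SD, n = 3 per group, log2 fold change -3.32, adjusted p = 5.70e-06 by limma). RFC3 itself came next, followed by the histone gene H3C4 (-2.31), the long noncoding RNA CCAT1 (-2.30), the nuclear receptor coactivator NCOA5 (-2.29) and CPS1, the first enzyme of the urea cycle (-2.15). EIF4EBP1, a repressor of cap-dependent translation (-1.93), UTP20, a factor of small ribosomal subunit processing (-1.91), SVEP1 (-1.82), the phosphodiesterase PDE1A (-1.82) and the antisense RNA VPS9D1-AS1 (-1.81) were also among them. H3C4 belongs to a family of near-identical genes, and VPS9D1-AS1 lies antisense to another gene, so their values are uncertain.

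NF-kB target chemokines and cytokines and interferon response genes rose together. Of 19 measured NF-kB targets 18 rose, with a median log2 fold change of 2.06 (camera adjusted p = 1.45e-13), and 18 passed when adjusted over the list alone. CXCL8, CCL5, CXCL1 and IL6 led them, and TNFAIP2, the member that did not pass and named after its value was seen, stood at 0.09. Of 22 measured interferon response genes 21 rose (22 adjusted over the list alone), with a median of 1.70 (camera adjusted p = 2.06e-12). ISG15 went from 33.3 ± 0.464 to 389 ± 85.6 FPKM and OASL, an RNA-sensing pathway protein, from 20.8 ± 1.23 to 191 ± 36.7 FPKM (SD, n = 3 per group). RSAD2 and OAS3 (2.55) also rose, while IFI44L, also named after its value was seen, stood at 0.44 and did not pass. MX1, MX2, CMPK2 and XAF1 were too low to be tested. Both lists also passed with an estimated correlation (adjusted p = 0.0244 for NF-kB and 0.0268 for interferon), and of the 23 lists they were the only ones that did.

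**Figure D1:**
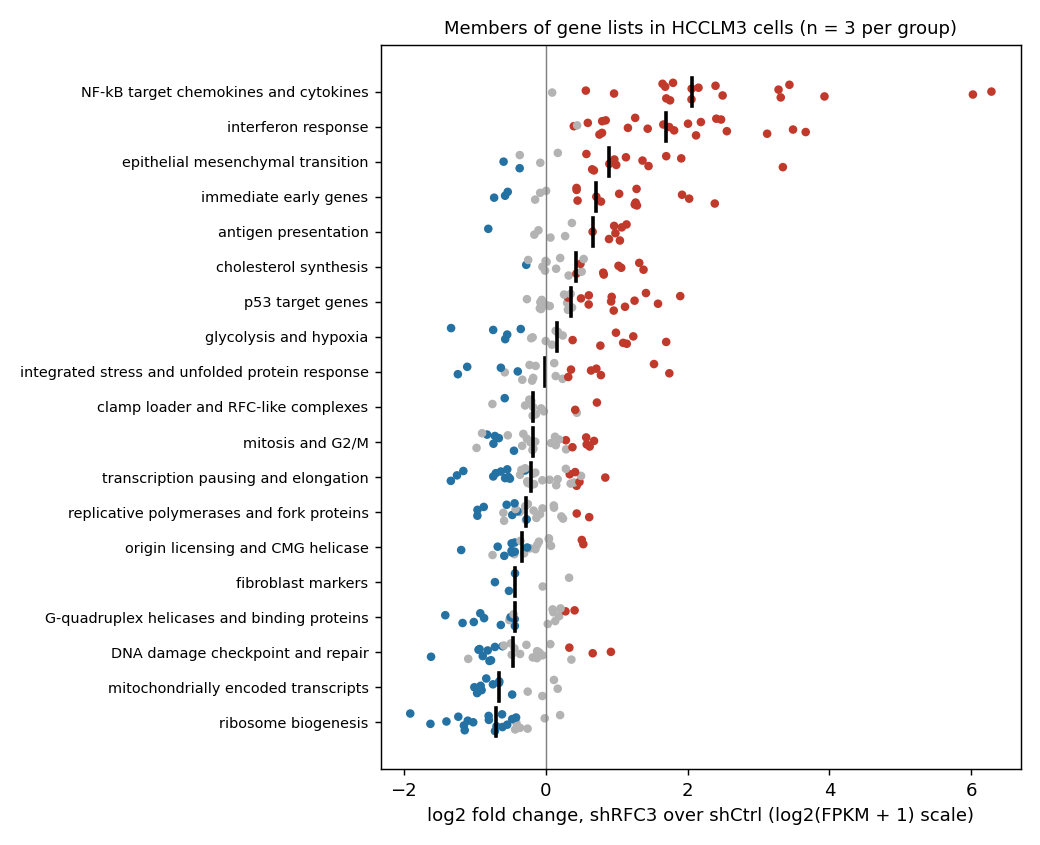
Log2 fold change (x axis, log2(FPKM + 1) scale, shRFC3 over shCtrl, n = 3 per group) of each measured member of the lists with at least 5 members; red and blue points passed the test as higher or lower, grey points did not, and black bars are list medians. The medians of the NF-kB and interferon lists lay at 2.06 and 1.70, and that of ribosome biogenesis at -0.69.

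Ribosome biogenesis genes fell. Of 23 measured 17 fell, 18 adjusted over the list alone, and none rose, with a median of -0.69 (camera adjusted p = 6.69e-08; adjusted p = 0.0912 with an estimated correlation). UTP20 (-1.91), NOP58, a core protein of box C/D ribonucleoproteins (-1.62), WDR43 (-1.40) and POLR1A, the largest subunit of RNA polymerase I (-1.23), fell most. The 13 mitochondrially encoded transcripts, read as a sign of RNA quality and cell state, moved with them: 9 fell and none rose, the same 9 in number adjusted over the list alone, with a median of -0.66 (camera adjusted p = 0.000662; adjusted p = 0.424 with an estimated correlation). MT-CYB, MT-CO2 (-0.97), MT-CO3 (-0.92) and MT-ATP6 (-0.90) led. These transcripts made up 21.4% to 24.6% of the summed FPKM in the shCtrl libraries and 15.3% to 18.3% in the shRFC3 libraries.

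Replication genes moved unevenly. Of 22 origin licensing and CMG helicase genes 9 fell and 2 rose, as many adjusted over the list alone (median -0.33, camera adjusted p = 0.0114; adjusted p = 0.136 with an estimated correlation). MCM3 (-1.19), MCM4 (-0.58) and the kinase CDC7 (-0.68) fell, whereas CDT1, which loads the MCM helicase (0.53), rose. CDC7 lost its call without any 1 of the shCtrl libraries and CDT1 likewise. Of 25 replicative polymerase and fork genes 8 fell and 2 rose, again as many adjusted over the list alone (median -0.28, camera adjusted p = 0.0273; adjusted p = 0.146 with an estimated correlation). POLD2 (-0.96) and POLA1 (-0.96) fell, and RRM2, a subunit of ribonucleotide reductase (0.61), rose. The other clamp loader and related genes did not move as a set: of 13 measured 2 rose and 1 fell, in both adjustments (median -0.18, camera adjusted p = 0.413). RAD9A (0.72) and CHTF18 (0.42) rose, HUS1 (-0.58) fell, and PCNA stood at -0.14 (adjusted p = 0.294 by limma). Mitosis genes also split, with 6 of 26 higher and 5 lower (6 and 6 adjusted over the list alone; median -0.18, camera adjusted p = 0.418), among them KIF20A (-0.74), TTK (-0.82) and NDC80 (-0.71) lower and BUB1 (0.68) higher.

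Of 24 measured p53 targets 12 rose and none fell, 13 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00111; adjusted p = 0.0912 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, went from 23.8 ± 1.63 to 73.6 ± 10.7 FPKM (SD, n = 3 per group), and BTG2 (1.90), PHLDA3 (1.41) and PLK3 (1.25) also rose. Of 26 DNA damage checkpoint and repair genes 9 fell and 3 rose, or 12 and 4 adjusted over the list alone (median -0.46, camera adjusted p = 0.0137; adjusted p = 0.522 with an estimated correlation). RAD50 (-1.61) and NBN (-0.93), partners in the MRE11 complex, and FANCD2 (-0.95) fell, and the kinase WEE1 (0.92) rose. Median fold changes fell with gene span, from 0.13 in the 4692 genes of shortest span to -0.10 in the 4692 of longest span (-0.02 without shRFC3 replicate 3), and several of these genes are long.

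G-quadruplexes are 4-stranded DNA structures, and the series set out to relate them to transcription. Of 19 genes for helicases and binding proteins of G-quadruplexes 9 fell and 2 rose, as many adjusted over the list alone, with a median of -0.44, and the set did not pass (camera adjusted p = 0.0507; adjusted p = 0.328 with an estimated correlation). Over the camera alternatives its adjusted p ranged from 0.0283 to 0.328, and fry, which tests the list on its own, gave 0.00700. Nucleolin, NCL, went from 78.3 ± 3.22 to 28.8 ± 1.90 FPKM (SD, n = 3 per group), and the helicases DHX9 (-1.17) and WRN (-0.92) and the zinc finger protein CNBP (-1.01) fell too. Transcription pausing and elongation genes gave 11 lower and 5 higher of 33 (11 and 6 adjusted over the list alone; median -0.20, camera adjusted p = 0.103), with AFF1 (-1.34) and AFF4 (-1.25), scaffolds of the super elongation complex, and SUPT16H of the FACT histone chaperone (-1.16) lower and ELL (0.84) higher.

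Among the proteins profiled by CUT&Tag, the TATA-binding protein gene TBP fell (-0.74, adjusted p = 0.00443 by limma). NELFA, a subunit of the pausing factor NELF, stood at 0.42 (adjusted p = 0.0264) and POLR2A, the largest subunit of RNA polymerase II, at -0.29 (adjusted p = 0.0341), both calls being lost without any 1 of the shCtrl libraries. CDK9 (0.40, adjusted p = 0.0732), CDK7 (0.35, adjusted p = 0.0573), NELFB (-0.26, adjusted p = 0.101), CCNT1 (-0.16, adjusted p = 0.526) and TOP1 (0.14, adjusted p = 0.591) did not pass by limma. Without shRFC3 replicate 3, all of these but CCNT1 passed.

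Mesenchymal, early response and cholesterol genes rose as sets under the preset correlation. Of 17 genes of the epithelial mesenchymal transition 12 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.90, camera adjusted p = 0.000662; adjusted p = 0.120 with an estimated correlation), with CCN2 (1.70) and the integrin ITGA5 (1.45) higher. Of 19 immediate early genes 13 rose and 3 fell, as many adjusted over the list alone (median 0.71, camera adjusted p = 0.00310; adjusted p = 0.346 with an estimated correlation). DUSP5 (2.38), FOSL1 (2.02), IER3 (1.92) and IER5 (1.29) rose. Of 19 cholesterol synthesis and uptake genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 0.0154; adjusted p = 0.146 with an estimated correlation). MSMO1 (1.38) and FDFT1 (1.07) were among them.

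The remaining lists did not pass in the main form of the test. Of 13 antigen presentation genes 7 rose and 1 fell, in both adjustments (median 0.66, camera adjusted p = 0.0637, from 0.0288 to 0.605 over the alternatives), with HLA-C (1.14), TAPBP (1.07), PSMB9 (1.05) and HLA-B (0.98) higher. Stress response genes went both ways, 7 higher and 4 lower of 20 in both adjustments (median -0.01 and mean 0.08, camera adjusted p = 0.825), with the chaperones DNAJB9 (1.74) and SDF2L1 (1.53) higher and SEL1L (-1.24) and PSAT1 (-1.11) lower. So did glycolysis and hypoxia genes, 7 higher and 5 lower of 20 in both adjustments (median 0.16, camera adjusted p = 0.403), with NDRG1 (1.70), CA9 (1.24) and ADM (1.14) higher and LDHA (-1.33) lower. Few liver genes were expressed in this line. Of 21 hepatocyte genes 3 could be tested, SERPINA1 (1.40), FOXA1 (0.83) and CEBPA (-0.65), all changed in both adjustments (camera adjusted p = 0.272), and of 14 oncofetal genes 4, LCN2 (1.47), SOX9 (0.91), CD24 (-0.71) and TSPAN8 (0.37), likewise (camera adjusted p = 0.163). Markers of cells that the line should lack were measured as well. CD14 and CSF1R of the leukocyte list did not pass in either adjustment (camera adjusted p = 0.825), PECAM1 alone of the endothelial list was measured and rose to 1.07 FPKM in both adjustments (camera adjusted p = 0.138), and 3 of 5 fibroblast markers, DCN, PDGFRB and LUM, fell in both adjustments (camera adjusted p = 0.103), while THY1 stood at 10.1 ± 1.71 FPKM with shCtrl and 12.8 ± 0.840 FPKM with shRFC3 (SD, n = 3 per group) and did not pass.

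The second comparison asked how the cells of a mouse liver tumour differed with the guide. In these 2 libraries hepatocyte-like cells took a smaller share and T, macrophage, endothelial and fibroblast-like cells a larger share with sgRFC3. Hepatocyte-like cells made up 38.7% (95% interval 37.5 to 39.8) of sgCtrl and 16.9% (16.0 to 17.8) of sgRFC3 cells, a ratio of 0.436 (0.408 to 0.467). T cell-like cells went from 5.21% to 14.7% (ratio 2.82, 2.51 to 3.18), monocyte or macrophage-like cells from 6.62% to 14.2% (2.15, 1.93 to 2.40), endothelium-like cells from 2.08% to 5.50% (2.64, 2.18 to 3.21), stellate cell or fibroblast-like cells from 2.88% to 5.96% (2.07, 1.75 to 2.46) and B cell-like cells from 2.19% to 4.81% (2.19, 1.81 to 2.66). There is no replicate of either tumour, so the spread between animals is unknown. With the looser cell filter the log2 ratio of shares was -0.58 in place of -1.20 for hepatocyte-like cells and 0.46 in place of 1.10 for macrophage-like cells, and the share of barcodes lost to the mitochondrial limit differed between the libraries (25.8% with sgCtrl and 16.7% with sgRFC3). Clusters were drawn and named anew under that filter, so these ratios also compare classes with different borders. The sgCtrl cells of the biliary epithelium-like cluster went from 592 to 1464, doublets included.

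**Figure D2:**
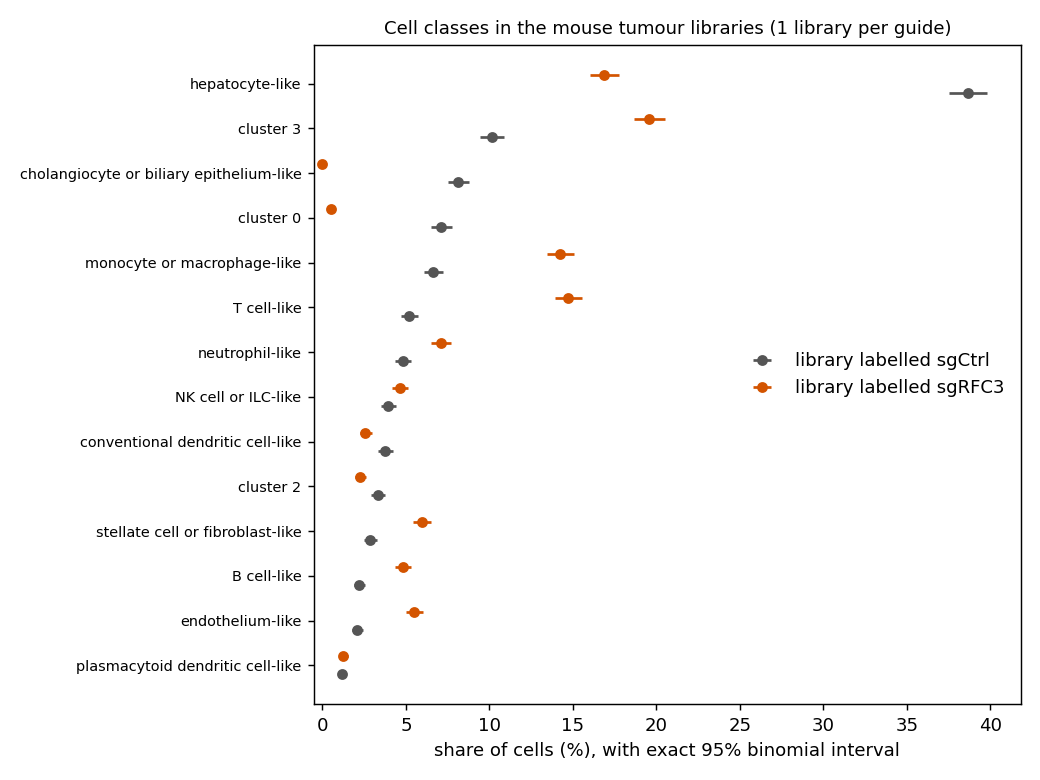
Share of cells (x axis, %) in each cell class or unnamed cluster of the library labelled sgCtrl (grey) and of that labelled sgRFC3 (orange), with exact 95% binomial intervals that cover counting error only. Hepatocyte-like cells made up 38.7% and 16.9%, T cell-like cells 5.21% and 14.7%.

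Neutrophil-like cells went from 4.81% to 7.10% (ratio 1.48, 1.29 to 1.70; log2 ratio 0.56, against 1.297 with the stricter cell filter), NK or ILC-like cells from 3.93% to 4.65% (1.18, 1.01 to 1.39) and plasmacytoid dendritic-like cells from 1.15% to 1.26% (1.10), while conventional dendritic-like cells went from 3.74% to 2.57% (0.687, 0.568 to 0.831). Of the unnamed clusters, cluster 3, with T cell markers such as Cd3e and Cd8a and led by Lef1 and Tcf7 among others, went from 10.1% to 19.6%. Cluster 2, with macrophage markers and led by Cd5l, went from 3.31% to 2.26%, and cluster 0, with hepatocyte markers and a median of 2640 UMIs in sgCtrl, went from 7.11% to 0.488%. Biliary epithelium-like cells, with Krt19 and Epcam, were 8.15% of sgCtrl and 0 of 7382 sgRFC3 cells, which allows a share of up to 0.0406%. They formed a single cluster, which may be a feature of the sgCtrl library. In it 6 of 10 biliary markers and also 6 hepatocyte markers were detected, so the name is uncertain. With the looser cell filter the biliary epithelium-like cluster held 1464 of 8820 sgCtrl cells and 1 of 8913 sgRFC3 cells, doublets included. Among cells outside the epithelial classes, T cell-like cells were 11.3% (10.3 to 12.4) with sgCtrl and 17.8% (16.9 to 18.8) with sgRFC3, macrophage-like cells 14.4% (13.2 to 15.6) and 17.2% (16.3 to 18.2), and endothelium-like cells 4.52% (3.84 to 5.28) and 6.66% (6.04 to 7.31). With cluster 2 counted among them the macrophage-like cells were 21.57% and 19.97%, so their direction in this measure turned with the naming. Intervals overlapped for B cell-like cells (4.76% and 5.82%), fibroblast-like cells (6.25% and 7.21%) and cluster 3 (22.02% and 23.7%). In this measure neutrophil-like cells (10.4% and 8.59%), NK or ILC-like cells (8.52% and 5.62%) and plasmacytoid dendritic-like cells (2.49% and 1.52%) were lower with sgRFC3, against the direction of their shares of all cells, and conventional dendritic-like cells (8.13% and 3.11%) and cluster 2 (7.19% and 2.74%) were lower in both.

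Rfc3 RNA was not lower in the hepatocyte-like cells of the library labelled sgRFC3. It stood at 36.3 CPM in sgCtrl and 41.9 in sgRFC3, a ratio of 1.15 (1.09 to 1.22). Over all cells it stood at 32.9 and 28.2 CPM (ratio 0.857, 0.816 to 0.901). Reads from the 3' end of a transcript do not show an edit of the gene, so these values do not check the label.

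The hepatocyte-like cells of the 2 libraries fell into different clusters, 1 and 7 in sgCtrl against 21 and 22 in sgRFC3. The class medians were alike (30688.5 and 31116.5 UMIs), but the clusters were not. Cluster 22 was shallow (median of 3241.5 UMIs), against 30141, 31536 and 35751.5 UMIs in clusters 1, 7 and 21. Shallow cells of cluster 0, with hepatocyte markers (518 sgCtrl and 38 sgRFC3 cells, doublets included), stayed unnamed and outside the class. At Leiden resolution 0.5 a shallow hepatocyte-like cluster (median of 2640 UMIs) held 605 sgCtrl and 284 sgRFC3 cells, while the deeper ones stayed apart (2879 and 4 cells, and 3 and 1018). With sgRFC3, the fetal serum protein Afp stood at 1159 CPM against 78.9 with sgCtrl (ratio 14.7, 14.3 to 15.1), Prg4, a secreted lubricant protein, at 195 against 11.7 (16.6, 15.6 to 17.8), Ces2a, a carboxylesterase, at 105 against 6.67 (15.8, 14.5 to 17.2), Gstm3, a glutathione transferase, at 200 against 16.3 (12.3, 11.6 to 13.0) and the water channel Aqp8 at 138 against 14.9 (9.30, 8.76 to 9.88). Afp, Prg4 and Gstm3 are also leading genes of the sgRFC3 clusters. Dlk1, an imprinted gene active in fetal liver, stood at 657 CPM with sgCtrl and at 3 UMIs in all with sgRFC3 (ratio 0.000113, 2.32e-05 to 0.000329), and Meg3, of the same imprinted cluster, at 3.38 with sgRFC3 against 120. Ccdc91 (2.30 against 182), Tmed6 (2.10 against 139) and Spink1, a trypsin inhibitor (9.83 against 230), were lower as well. As a list, oncofetal markers had 5 genes higher and 9 lower, and a median log2 ratio of -1.37 that lay below each of 10000 random lists but had an interval from -3.76 to 0.75, with Krt19 (-5.60) and Tspan8 (-3.79) lower and Afp higher.

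**Figure D3:**
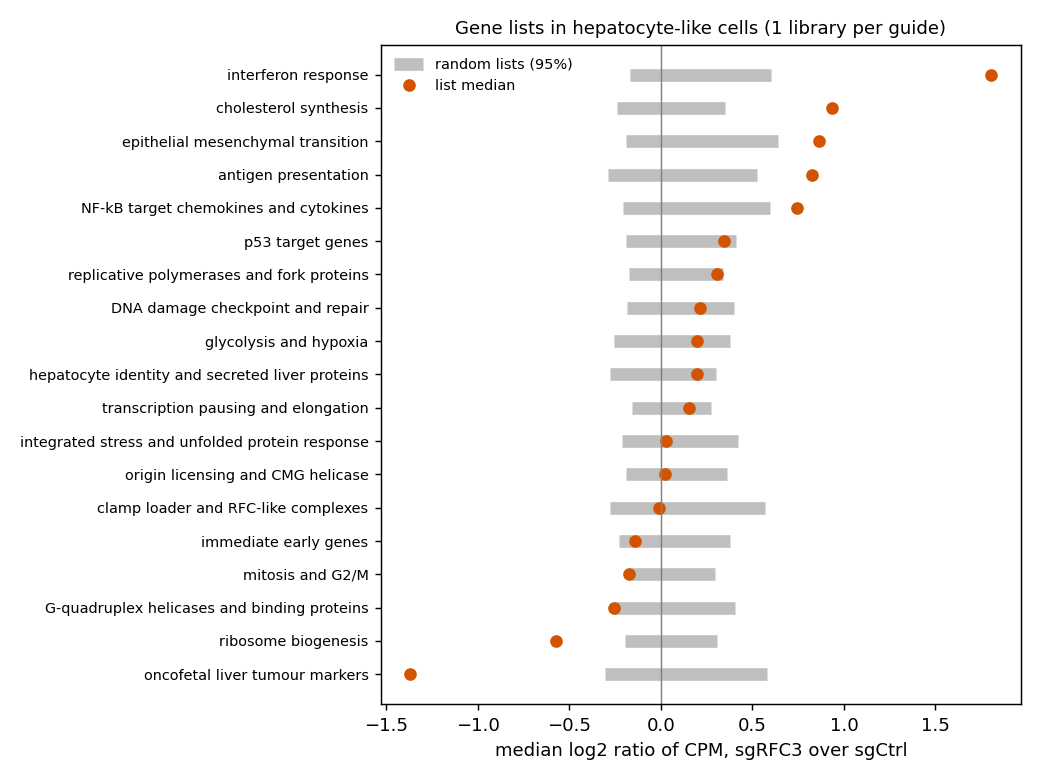
Median log2 ratio of CPM (x axis, sgRFC3 over sgCtrl) of each gene list in hepatocyte-like cells (orange points), with the central 95% of 10000 random lists matched on size and expression (grey bars). Interferon response genes lay at 1.81 and ribosome biogenesis genes at -0.57, both outside the range of random lists.

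Interferon response genes were higher in the sgRFC3 hepatocyte-like cells, 22 of 22, with a median log2 ratio of 1.81 (percentile 100), and NF-kB targets stood at 0.74 (percentile 99.3, 13 of 17 higher). Ifih1, an RNA sensor, stood at 77.9 against 11.7 CPM, Rsad2 at 25.9 against 4.24, and the chemokines Ccl5 at 147 against 48.5 and Cxcl2 at 121 against 40.3. Antigen presentation genes (0.83, percentile 99.9), with B2m at 363 against 129 CPM, and epithelial mesenchymal transition genes (0.87, percentile 99.7), with Sparc at 46.4 against 8.08, were higher too. Markers of other cells moved with these lists in the same cells: leukocyte markers stood at 1.49, endothelial markers at 1.79 and fibroblast markers at 5.04. Ptprc, the leukocyte surface protein CD45, gave 69.9 against 19.8 CPM in hepatocyte-like cells and 1139 in the other sgRFC3 cells, and Col1a1 58.3 against 1.46, with 1151 in the other cells.

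Cholesterol synthesis genes were higher in the sgRFC3 hepatocyte-like cells, 17 of 19, with a median of 0.93 (percentile 100). Sc5d stood at 239 against 80.1 CPM, Fdps at 287 against 112 and Insig1 at 280 against 112, each above its level in the other sgRFC3 cells. Ribosome biogenesis genes were lower, 17 of 23, with a median of -0.57 (percentile 0), among them Ppan (44.7 against 132 CPM), Polr1b (20.2 against 57.7), Rrp9 (18.6 against 48.9) and Gnl3 (67.8 against 145). G-quadruplex helicases and binding proteins lay at -0.26 (percentile 2.38), with Hnrnpa1 at 238 against 435 and Blm at 52.1 against 29.9 CPM. Mitosis genes lay at -0.17 (percentile 2.01), with Kif11 at 57.4 against 104 and Top2a at 126 against 202. Mitochondrially encoded transcripts lay at 0.40 (percentile 97.7).

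The other lists lay within the central 95% of random lists in these cells. They were replicative polymerases (0.30, percentile 96.0, Rrm2 64.2 against 35.5 CPM), p53 targets (0.34, 94.7, Plk2 23.4 against 7.22), hepatocyte identity (0.20, 88.3), glycolysis and hypoxia (0.20, 81.5), transcription elongation (0.15, 81.1, Ell2 60.1 against 33.6), DNA damage (0.21, 79.3, Fanca 15.3 against 5.81), origin licensing (0.02, 36.5), stress response (0.03, 35.4), clamp loader (-0.01, 28.0, Rfc4 131 against 49.9) and immediate early genes (-0.14, 8.50, Fos 251 against 682).

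In monocyte or macrophage-like cells (clusters 10, 11 and 17) Pf4 stood at 2989 CPM with sgRFC3 and 241 with sgCtrl (ratio 12.4, 11.5 to 13.4), the chemokines Cxcl3 at 474 against 6.91 (68.5, 43.8 to 114) and Ccl8 at 229 against 19.6 (11.7, 8.90 to 15.6), and Ly6a at 218 against 25.1. Ppbp stood at 281 against 0.364, the latter a single UMI (772, 138 to 30510); Pf4 and Ppbp are known from platelets. The proteases Mmp13 (54.7 against 245) and Mmp12 (305 against 1198), Vcam1 (62.7 against 223), Hspa1a (650 against 2259) and the class II gene H2-Eb1 (566 against 1958) were lower. Pf4 and Ccl8 lead cluster 10 and Mmp12 leads cluster 11, and 796 of the cells of cluster 10 came from sgRFC3 against 243 from sgCtrl.

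Stellate cell or fibroblast-like cells were also in different clusters: cluster 5 held 204 sgCtrl and 198 sgRFC3 cells, and cluster 19, with collagen, Lum and Pdgfra, 4 and 245, doublets included. Fabp7 (5.10 against 332 CPM), Colec11 (34.1 against 690), Higd1b (24.4 against 459), Sema5b (8.50 against 122) and Sparcl1 (37.3 against 530) were lower with sgRFC3. Ptgs2, the inducible cyclooxygenase (159 against 0.811, the latter a single UMI, ratio 196, 35.1 to 7736), Mfap5 (303 against 4.05), Igfbp6 (118 against 2.43), Fbln2 (518 against 13.8) and Ly6a (203 against 6.49) were higher. Colec11, Higd1b, Mfap5 and Fbln2 are leading genes of these clusters.

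In T cell-like cells the transcription factors Tbx21 (192 against 63.8 CPM), Bach2 (435 against 148) and Trerf1 (166 against 50.2), with Phactr2 (104 against 28.5) and Gm42418, which overlaps ribosomal RNA sequence (4532 against 1236), were higher with sgRFC3, and Penk (19.2 against 133), Cd83, Igkc, Tmem176b and Bsg (116 against 302) were lower. This class pools clusters 9, 14 and 16, with 151, 59 and 164 sgCtrl and 355, 56 and 678 sgRFC3 cells, doublets included. The different mix of clusters may enter these values. In sgCtrl, Igkc stood at 118 CPM in T cell-like cells and 129.5 CPM in the other cells, and Tmem176b at 101 and 184 CPM. RNA from other cells may therefore enter the values of Igkc and Tmem176b. In NK or ILC-like cells the transcription factor Myb (188 against 60.3), Yes1 (119 against 32.1), Antxr2, Mid1 and Gm47283 were higher and the granzyme Gzmc (83.8 against 327), Ech1, Slc25a4, Ubb and Dnajb1 lower. In cluster 3 Myb (115 against 39.4), Ppm1l, Arhgap31, Gm47283 and Trps1 were higher and Btg2 (357 against 733), Ubb, Rgs1 and Fos (489 against 935) lower. In neutrophil-like cells, whose median depth was 1551.5 and 1862 UMIs, Cxcl3 (797 against 144), Tmem267, P2rx7, Abca1 (160 against 30.7) and Fmnl2 were higher and G0s2 (1082 against 3516), Hist1h4i, Fos (383 against 1387), Snhg1 and Gdf15 lower. The higher genes named here were also higher, and most of the lower ones lower, in the cells outside their class or cluster. Those cells were pooled over classes whose mix differed between the libraries. Hepatocyte-like cells held 89851025 of 131637149 UMIs in sgCtrl and 40479151 of 90712567 UMIs in sgRFC3. The levels outside a class therefore cannot show whether any other class changed. Outside NK or ILC-like cells Ech1 stood at 82.7 against 169 CPM, Dnajb1 at 270 against 607 and Ubb at 784 against 1096. Bsg stood at 249 against 562 outside T cell-like cells. Gzmc, Penk, Cd83, Igkc and Rgs1 were not lower outside their class or cluster.

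Cells with mitosis genes were about as common among hepatocyte-like cells of both libraries. At a common depth of 1000 UMIs, 41.5% (39.6 to 43.3) of sgCtrl and 38.1% (35.4 to 40.9) of sgRFC3 hepatocyte-like cells had UMIs of at least 2 mitosis genes, or 98.9% and 93.7% without thinning. The share was 10.7% and 17.0% in endothelium-like cells, 20.4% (16.4 to 24.8) and 15.7% (13.6 to 18.1) in T cell-like cells, and 8.65% (6.28 to 11.6) and 5.42% (4.13 to 6.97) in macrophage-like cells. It was 19.4% (14.8 to 24.7) and 6.32% (3.31 to 10.8) in conventional dendritic-like cells, 17.1% and 13.1% in NK or ILC-like cells, 14.9% and 12.1% in cluster 3 and 8.44% and 6.59% in cluster 2. As counts, it was 22 of 157 and 14 of 355 B cell-like cells, 18 of 82 and 7 of 93 plasmacytoid dendritic-like cells, and 26 of 206 and 88 of 440 fibroblast-like cells. Without thinning the shares were 79.5% and 63.7% in conventional dendritic-like, 32.5% and 24.8% in B cell-like and 51.3% and 49.9% in macrophage-like cells. The log2 ratios of these shares were -0.32, -0.39 and -0.0402, in place of -1.62, -1.83 and -0.67 with thinning. In neutrophil-like cells it was 11.0% (7.94 to 14.8) and 4.58% (2.96 to 6.74). The direction in neutrophil-like cells turned under the stricter cell filter (log2 ratio 0.47).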

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

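These results were picked out because a gene list moved in opposite directions in cell classes of the same 2 tumours. With 1 library per guide the differences were not tested. Cholesterol synthesis genes lay higher with sgRFC3 in hepatocyte-like cells (median log2 ratio 0.93) and lower in B cell-like (-0.46), NK or ILC-like (-0.41), T cell-like (-0.41), monocyte or macrophage-like (-0.29), neutrophil-like (-0.53) and plasmacytoid dendritic-like cells (-0.62). Hepatocyte identity genes lay lower still in these 6 classes (-1.05, -1.17, -1.08, -1.40, -1.47 and -1.23), each below every random list, so free RNA of hepatocytes may enter these values. The B cell-like and macrophage-like values of the cholesterol list lay within the central 95% of random lists (percentiles 4.08 and 3.72), and the sign turned in NK or ILC-like cells with thinned expression (0.0227) and in macrophage-like cells at Leiden resolution 0.5 (0.0369). Replicative polymerase and fork genes lay higher in hepatocyte-like cells (0.30) and lower in B cell-like (-1.02), conventional dendritic-like (-0.47), neutrophil-like (-0.43) and plasmacytoid dendritic-like cells (-1.26). The hepatocyte-like and neutrophil-like values lay within the central 95% of random lists (percentiles 96.0 and 4.01).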

How the results depend on the processing

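RFC3 stayed lower under all 12 alternatives (log2 fold change -2.45 to -2.08 with 1 library left out), and the NF-kB (2.02 to 2.21) and interferon (1.64 to 1.84) lists passed under every alternative. For the other results named here the cause was not tested. With 1 library left out, changed genes ranged from 3949 to 7520, lower genes from 1590 to 3385, lists from 11 to 13, the G-quadruplex list from -0.51 to -0.21 and antigen presentation from 0.47 to 0.79, the last 2 passing in 4 of 6 such fits each. A pseudocount of 0.1 gave 2056 genes with at least 2-fold change, and the test against a 1.5-fold change 777 genes, 564 higher and 213 lower. Same-numbered libraries of the 2 hairpins correlated in their deviations at -0.0682, 0.150 and -0.00754, and not every library correlated best with its own number, so the numbers were not taken to pair them. With the replicate block 5180 genes and 13 lists passed, the added lists being G-quadruplex (-0.44, adjusted p = 0.0315) and antigen presentation (0.66, adjusted p = 0.0288); over the camera alternatives the adjusted p ranged from 0.0283 to 0.328 for the first and from 0.0288 to 0.605 for the second, and fry gave 0.00700 and 0.0414. The same 2 lists also passed by camera elsewhere: G-quadruplex without the filter (-0.44), after median-of-ratios scaling (-0.47) and, in a form added after seeing the data, with a trended variance (-0.44, adjusted p = 0.0467), and antigen presentation at a mean of at least 1 FPKM (0.78) and after quantile normalization (0.39). Without the filter elongation (-0.20) and fibroblast markers (-0.28) passed too, and after quantile normalization the mitochondrial list did not (-0.30). With an estimated correlation 2 lists passed, and these did not: licensing (-0.33), polymerases (-0.28), p53 (0.36), DNA damage (-0.46), immediate early (0.71), ribosome biogenesis (-0.69), cholesterol (0.43), mesenchymal transition (0.90) and mitochondrial (-0.66). Fry in place of camera called 19 lists, adding G-quadruplex (-0.44), elongation (-0.20), stress response (-0.00996), glycolysis (0.16), hepatocyte identity (0.83), oncofetal (0.64), antigen presentation (0.66), endothelial (0.77) and fibroblast markers (-0.43) and losing DNA damage (-0.46); it tests each list on its own, against no other genes. Of the comparisons of named genes with 1 library left out 622 kept their call, 30 lost it and 5 gained it, and of the others 645, 9 and 1. In the tumours 69 of the alternative shares, 82 of the Rfc3 levels and 97 of the proliferating shares stayed within the counting interval. Of the list medians 1823 stayed within the interval over the list members, which can be wide, while 53 moved out of it and 12 were reversed. With the stricter cell filter the log2 ratio of shares was -4.57 for cluster 0, 1.81 for endothelium, -1.67 for hepatocyte-like and 1.297 for neutrophil-like cells, and in neutrophil-like cells the proliferating share (0.47) and the stress response (0.11) changed sign. With the looser filter it was 1.04 for endothelium, -0.58 for hepatocyte-like and 0.46 for macrophage-like cells, Rfc3 lay at 0.0814 in hepatocyte-like and -1.20 in fibroblast-like cells, and in the latter licensing (-0.0782), cholesterol (-0.0250) and hepatocyte identity (-1.05) changed sign. Clusters were drawn and named anew under the looser filter. At Leiden resolution 0.5 the shares were -1.44 for hepatocyte-like and 0.88 for macrophage-like cells, and in the latter the clamp loader (0.17), licensing (0.12) and cholesterol (0.0369) lists changed sign. Of the forms added after seeing the data, naming version 2 gave shares of 2.01 for T cell-like and 0.73 for macrophage-like cells, with immediate early genes in T cells (0.31) and the clamp loader in macrophages (0.00812) changing sign, and version 3 gave 1.16, 0.73 and 0.00812. Without thinning the proliferating share lay at -0.39 in B, -0.32 in conventional dendritic and -0.0402 in macrophage-like cells, and with thinned expression licensing in B cells (0.55) and cholesterol in NK cells (0.0227) changed sign. No paired analysis was possible because there is 1 mouse library per guide. The quasi-likelihood test of edgeR, planned for read counts, was not run on FPKM. Depth behind the FPKM values is unknown, and B and neutrophil-like cells, with medians from 1551.5 to 3176 UMIs, are the shallowest named classes.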

Other observations

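Of the tests below, those on leukocytes, on scaling and on shRFC3 replicate 3 for the interferon and NF-kB lists, on a stronger form of the change in replicate 3, and on histone genes were chosen only after the result was seen. Their predictions were also written afterwards.

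Histone genes were looked at as a family only after H3C4 was seen among the genes that fell most. Of 46 measured 17 fell, 3 rose and 26 did not pass, with a median log2 fold change of -0.31 (camera p = 9.60e-05, and p = 0.0112 with an estimated correlation). H3C4 (-2.31), H3-2 (-1.72), H1-3 (-1.09) and H2AC6 (-1.07) fell most, and H2AC18 (0.81), H2AC19 (0.78) and H2BC17 (0.48) rose. Their transcripts share sequence and many lack a poly(A) tail, so single values are uncertain.

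In the tumours, interferon response genes lay above random lists in other classes too, with medians of 1.04 in conventional dendritic-like, 0.58 in NK or ILC-like and in cluster 3, 0.50 in T cell-like and 0.44 in monocyte or macrophage-like cells. In endothelium-like (0.16), fibroblast-like (0.0662), B cell-like (0.22), neutrophil-like (0.38) and plasmacytoid dendritic-like cells (0.49) and in cluster 2 (0.16) they lay within the central 95%. Fibroblast markers lay at 4.37 in T cell-like cells, 4.47 in macrophage-like cells and 3.43 in cluster 3, and leukocyte markers at 0.76 in conventional dendritic-like cells, 0.67 in cluster 3, 0.61 in NK or ILC-like and 0.56 in T cell-like cells, all above the central 95%. Ribosome biogenesis genes lay lower in neutrophil-like (-1.46), macrophage-like (-0.91) and conventional dendritic-like cells (-0.58), and hepatocyte identity genes lay lower still (-1.47, -1.40 and -1.60), below every random list. Mitosis genes lay higher in endothelium-like cells (0.80) and lower in B cell-like (-1.72) and conventional dendritic-like cells (-0.87). In the endothelium-like cells leukocyte markers lay at 1.99, 9 of 9 higher, and endothelial markers at -0.35, so other cells or free RNA may enter all of these differences.

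For the interferon and NF-kB lists in the cell line, 3 technical explanations were weighed. Leukocytes in the cultures would have raised leukocyte markers, whose sum went from 1.87 to 2.12 FPKM (ratio 1.13). CD14 (1.01 and 1.17 FPKM) and CSF1R (0.737 and 0.595 FPKM) made up most of it. The ratio stayed under the 2-fold bound against leukocytes, but the sum passed the bound for them, 1 FPKM, with both hairpins. It therefore does not decide. Of the markers too low to be tested, ITGAM (0.0546 to 0.293 FPKM), PTPRC and CD3D rose, TYROBP, CD79A, LYZ and CD3E fell, and MS4A1 stayed at 0. Under 2 rescalings the smaller list median was 1.65, and without shRFC3 replicate 3 it was 1.84, so neither scaling nor that library alone accounts for them. The columns name 1 hairpin against RFC3, so a response to the hairpin sequence itself stays open. The biological explanation, loss of RFC3, cannot be separated from it here.

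For shRFC3 replicate 3, which stood apart, gene span was weighed against a stronger form of the same change. Its differences from the other 2 shRFC3 replicates correlated with gene span at -0.306 and -0.341, against at most 0.139 in size between other replicates. This met the bound predicted for a difference in RNA integrity or fragments. Span was the length of the locus, introns included, and not of the transcript. The correlation therefore does not tell such a difference from other causes that follow span. The prediction had concerned deviations from the group mean (-0.332, and 0.244 and 0.309 in replicates 1 and 2), but these are tied to each other by the centring, so single differences were used; the bound was met either way. Its difference from replicate 2 correlated at 0.0752 with the change in replicate 1, and that from replicate 1 at 0.0981 with the change in replicate 2, below the bound of a stronger form. On the first principal component, however, it lay farther from shCtrl (44.9, against 29.3 and 29.9), with the lowest RFC3 (1.88, against 3.78 and 3.51 FPKM), so a stronger form of the change is left open.

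For the hepatocyte-like cells in different clusters, depth and free RNA were weighed. Thinning every cell to the same depth moved the Afp log2 ratio by 0.285, from 3.88 to 3.59. Thinning alters such a ratio of sums mainly through the weight of each cell, and the thinned cells were not clustered again. The value therefore cannot decide whether depth set the clusters apart. Afp in the T cell-like cells of sgRFC3 was 4.26% of its level in hepatocyte-like cells, but Afp is a hepatocyte gene that other cells would not supply. Markers that other cells could supply also lay higher in the sgRFC3 hepatocyte-like cells (fibroblast 5.04, endothelial 1.79 and leukocyte 1.49), so free RNA is left open. With 1 library per guide, differences between tumours or animals cannot be set apart from the guide.

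Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real grouping, the real grouping itself (5898, against at most 7 in the others), and 1 as many lists (11, against at most 8). With 10 splits no p below 0.1 can be reached, and every other split puts libraries of both hairpins in each group, so it keeps part of the difference between them.

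Hypothesis: genes of longer span fall more in shRFC3 cells. The rank correlation of fold change with span was -0.108 without shRFC3 replicate 3, past the bound of the prediction. A condition added after seeing it, that it exceed the correlations between replicates (up to 0.139 in size), was not met, so the hypothesis stays undecided.

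Hypothesis: the interferon and NF-kB responses of the cell line are also present in the sgRFC3 tumour cells. Their medians in hepatocyte-like cells lay at percentiles 100 and 99.3 of random lists, past the bound of the prediction, but leukocyte markers lay at 99.9 in the same cells. The rule was tightened after these values were seen, so that such markers leave the result open. Relative to other cells, the interferon genes stood 3.27 times as high as leukocyte markers, which stood at 7.02%, between the bounds for free RNA and against it.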
